A study of Homo sapiens with 12 samples.

How the data were processed

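The labels describe total RNA from Saos2 Tet-Off clones B3 and F7, each with and without doxycycline, on 12 arrays in 4 groups of 3. Per the labels, the RNA was turned into double-stranded cDNA, transcribed in vitro with biotin-labelled UTP and detected with Cy5-streptavidin. The deposited values are probe intensity on a linear scale, 1 colour. Each array's median was about 1 and 299 to 553 values per array were 0 or below, so the values had been scaled to the median and, since values below 0 occur, background-corrected before deposit; scanner, background method and normalization are not given in the sources used here. The value -9999 marks a missing cell (139 to 260 per array). Detection calls were not used here.

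Values at or below 0 and missing cells were set aside, the rest were taken as log2, and no further normalization was applied. A probe was tested when each group had at least 2 values, which kept 54215 of 54359 probes. The median of all tested values was log2 0.0228. Gene names came from the platform annotation paired with the table: 23472 probes had 1 symbol, 905 had several and 29982 had none listed. Of the probes with 1 symbol, 23434 matched a RefSeq gene table (GRCh38.p14) through the gene identifier, with the same symbol in each case, and no name was taken from a probe with several. For 1 value per gene, the probe with the highest mean log2 value was used, which gave 18227 genes. Row and column of a probe were read from its number, which fits a grid of 504 rows and 112 columns; this reading is inferred.

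Each comparison was a contrast in one limma fit (version 3.58.1, R 4.3.3) of all 12 arrays, with lmFit, contrasts.fit and eBayes with a mean-variance trend, so that all groups share one estimate of the spread. P-values were adjusted by Benjamini-Hochberg over all tested probes, and a probe was called at an adjusted p under 0.05. Comparisons were B3 -Dox against B3 +Dox, F7 -Dox against F7 +Dox, the difference of these, B3 -Dox against each F7 group, B3 +Dox against F7 +Dox, and the overlap of the calls of B3 -Dox against the 3 other groups. No replicate block was used in these fits; the fit with a block, and the check of whether the replicate numbers pair the arrays, are given with the alternatives in the closing section. Gene lists (30, with 627 distinct genes, 547 of them measured) were fixed beforehand and tested with camera at a preset correlation of 0.01 on 16793 genes, adjusted over the lists of a comparison.

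The genes named follow a rule fixed before the data were examined, as were the design and the main alternatives. It takes genes with 1 symbol, the higher group at or above the median of tested values, an adjusted p under 0.05 and no overlap between the arrays of both groups: the 10 largest rises and 10 largest falls in B3 -Dox against B3 +Dox, and 5 and 5 in the other named comparisons. No absence of overlap was asked for the difference of responses. Where fewer than 5 genes passed, the 5 rises and 5 falls with the smallest p are given as not passing. YEATS4 is always named. From each list described, up to 2 called rises and 2 called falls, or the 2 members with the smallest p, are named, and uncharacterised loci are passed over. Calls against F7 +Dox and probes without a listed gene were named after their values were seen.

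The fit was tested on simulated data for B3 -Dox against B3 +Dox (49177 probes, real means and spreads, changed probes drawn from the brighter part of the array). It recovered 5 of 100 changes of 2-fold and 51 of 100 changes of 4-fold with 0 false calls. With a replicate block it recovered 38 and 57 with 4 false calls. The simulated arrays carried replicate effects and a spread taken from the fit with that block, so the gain with the block was built in. Alternatives were quantile normalization, scaling to the 75th percentile, leaving out the dimmest 25% of probes, a floor at the 10th percentile (intensity 0.377), only probes with all 12 values, averaging per gene, no trend, only the arrays compared, the replicate block and leaving out each array. Alternatives without F7 +Dox replicate 3 where the comparison does not contain it, the block combined with another change, and leaving out each array in the list tests were chosen after the data were seen. Which gene lists are described in detail was also chosen after the list results were seen.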

Results

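Total RNA of Saos2, a human osteosarcoma cell line that lacks functional p53, was measured on 12 arrays of one colour. The cells carry a Tet-Off system, in which doxycycline (Dox) in the medium keeps a response plasmid silent and its removal turns the plasmid on. In clone B3 the plasmid carries GAS41, the gene now named YEATS4, whose protein reads acetylated histones and belongs to the SRCAP and TIP60 chromatin complexes. Clone F7 carries the response plasmid without that gene. Each clone was grown with and without doxycycline, which gives 4 groups of 3 arrays. Nothing in the labels says whether the replicates were separate cultures. The study set B3 -Dox against B3 +Dox to find genes that follow GAS41, and against both F7 groups to set aside genes that follow doxycycline itself. The table held 54359 probes per array, with median intensities of 1.005 to 1.008, so a value of 1 is the level of a typical probe. The number of arrays, 3 per group, limits the precision of every value below.

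Correlations across bright probes (5900 probes with a median of at least 8) with the other 11 arrays averaged 0.937 to 0.961 for 11 of the arrays and 0.895 for F7 +Dox replicate 3. On that array 81 bright probes lay more than 4-fold from the median of the 12 arrays, 69 of them lower, against 1 to 14 on each other array. Most of the 81 lay near one edge: 64 were among the 214 bright probes of columns 1 to 9 and rows up to 220, as read from the probe numbers.

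**Figure D1:**
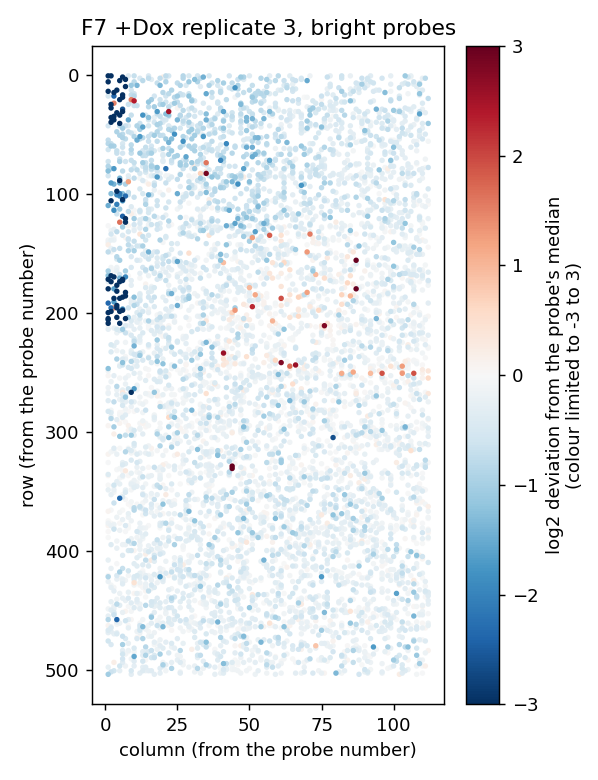
Position of each bright probe on the array of F7 +Dox replicate 3, by row and column as read from the probe number, coloured by its log2 deviation from the median of the 12 arrays. The darkest blue points, the lowest deviations, cluster at the left edge, where 64 bright probes deviated more than 4-fold.

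YEATS4 was not higher in the arrays labelled B3 -Dox. Its only probe read 30.8 ± 6.54 (SD, n = 3) there and 31.9 ± 7.31 (SD, n = 3) in B3 +Dox, against 29.5 in F7 +Dox and 36.0 in F7 -Dox. The log2 difference between B3 -Dox and B3 +Dox was -0.048 (SE 0.196, 95% interval -0.472 to 0.377, limma adjusted p = 1), and the upper bound corresponds to 1.30-fold. An exact two-sided permutation test gave p = 0.8, where 3 arrays against 3 cannot give less than 0.1. The gene lies on chromosome 12 from 69359743 to 69427072 (GRCh38.p14). Whether the probe lies in the part of the transcript that the plasmid carries is not given in the sources used here, so this level checks the labels only if it does. Groups are therefore named below as labelled, and every direction drawn from B3 -Dox rests on the label.

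**Figure D2:**
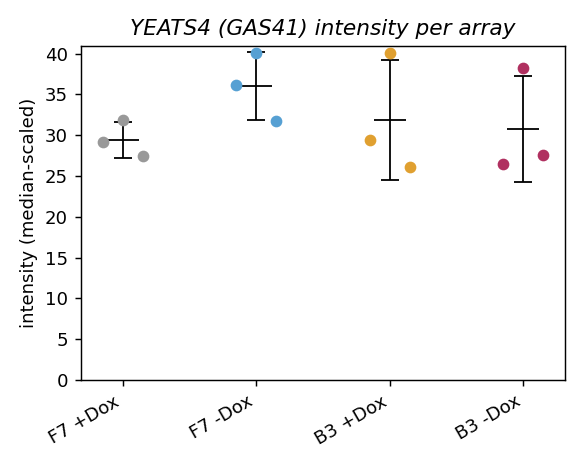
YEATS4 intensity (each array's median is about 1) on the 12 arrays, 3 per group; black marks are means with SD. The arrays labelled B3 -Dox lie between 26.5 and 38.3 and overlap those of B3 +Dox, from 26.1 to 40.1.

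Between the arrays labelled B3 -Dox and B3 +Dox, the comparison that asks what follows GAS41, EEF1A2 was the only named gene that passed the test. EEF1A2, the form of translation elongation factor 1 alpha found mainly in nerve and muscle, fell by 1.31 on the log2 scale (SE 0.164, limma adjusted p = 0.0316), from 56.04 ± 1.99 to 22.8 ± 3.71 (SD, n = 3 each). The other 4 called probes rose and have no listed gene. The strongest of them, probe 73082, went from 4.05 to 37.3, a log2 difference of 3.20 (SE 0.202, limma adjusted p = 5.72e-05). Probes 62066, 53073 and 318014 rose by log2 2.15, 2.06 and 1.22. All 5 called probes differed in the same direction between F7 -Dox and F7 +Dox, but not by like amounts. There EEF1A2 differed by log2 -1.21 and probe 73082 by 1.20. Probes 62066, 53073 and 318014 differed by only 0.29, 0.21 and 0.20. EEF1A2 lost its call when any 1 of the 6 arrays was left out, with limma adjusted p from 0.0838 without B3 +Dox replicate 2 to 0.277 without B3 +Dox replicate 1. It also lost the call after quantile normalization (limma adjusted p = 0.0775), averaged per gene (0.0762), without the mean-variance trend (0.841) and with only the arrays compared (0.565). With a replicate block EEF1A2 kept its call (limma adjusted p = 0.00589).

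The remaining genes named by the fixed rule for this comparison did not pass in the fit without a replicate block and are given as values; with such a block most did, as given among the alternatives. MMP9, a secreted gelatinase, averaged 12.6 in the arrays labelled B3 -Dox and 4.45 in B3 +Dox (log2 1.49, SE 0.214, limma adjusted p = 0.0687). NPR1, the receptor for atrial natriuretic peptide, averaged 60.9 against 24.9, and PLCXD2, a protein with a phospholipase C domain, averaged 99.6 against 33.4. LMO4, a LIM-only partner of transcription factors, differed by log2 0.99, and LLCFC1 by log2 1.34. Lower values in the arrays labelled B3 -Dox were those of POLI, a DNA polymerase that copies past lesions (log2 -0.96), SFN, the 14-3-3 sigma protein (log2 -0.84), EIF3C, a subunit of translation initiation factor 3 (log2 -1.03), and PBK, a kinase active in mitosis (log2 -0.79). Their limma adjusted p lay between 0.152 and 0.404, as did those of NPR1, PLCXD2, LMO4 and LLCFC1. SFN also fell in F7, from 46.6 to 27.6 (log2 -0.75), about as much as in B3, from 43.7 to 24.5. In F7 PBK went from 23.3 to 21.8 and POLI rose from 7.13 to 9.99. MMP9, NPR1, PLCXD2, LMO4 and LLCFC1 passed after quantile normalization, with limma adjusted p of 0.00499, 0.000456, 0.00151, 0.0192 and 0.00549.

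**Figure D3:**
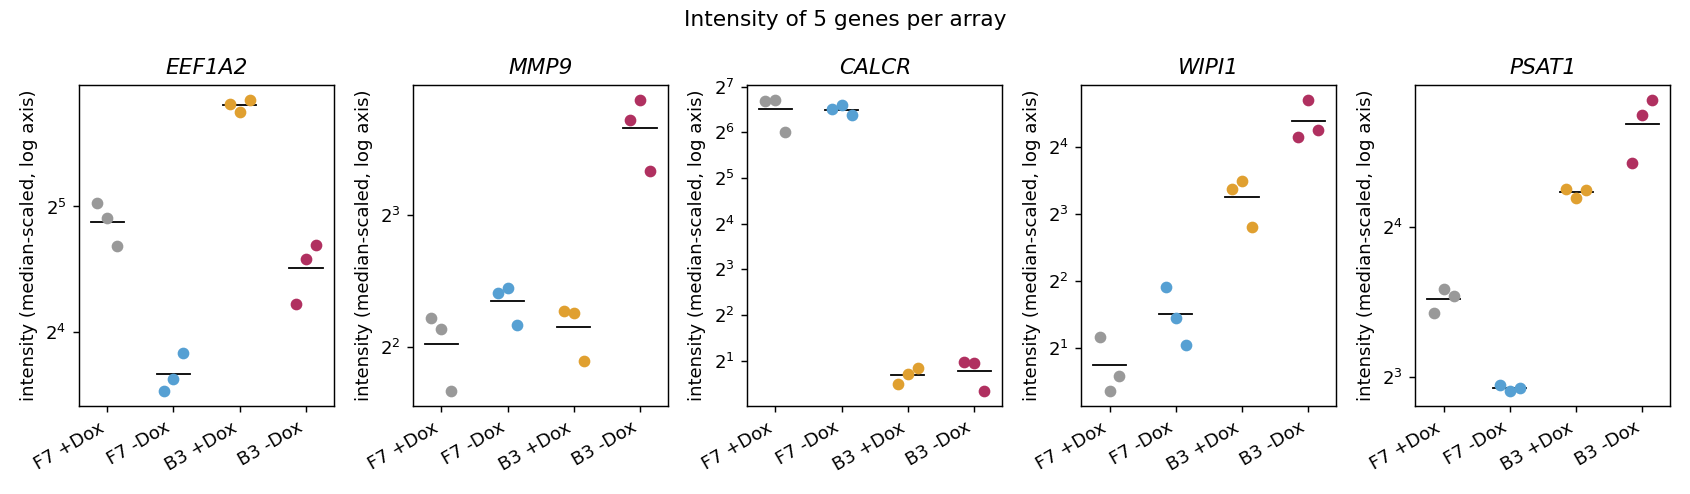
Intensity (each array's median is about 1, log axis) of EEF1A2, MMP9, CALCR, WIPI1 and PSAT1 on the 12 arrays, 3 per group; bars are group means. EEF1A2 was lower without doxycycline in both clones, and CALCR was near 90 in both F7 groups and under 2 in both B3 groups on average.

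None of the 30 gene lists fixed beforehand passed between the arrays labelled B3 -Dox and B3 +Dox. The smallest camera adjusted p was 0.229, shared by S phase and DNA replication (24 of 30 measured genes lower, median log2 -0.31), mitosis and spindle (17 of 28 lower, median log2 -0.16) and ribosome biogenesis (12 of 15 lower, median log2 -0.15). No gene of these 3 lists passed the test. ORC1, which marks replication origins, had 3.27 against 5.79, and CCNE1, the cyclin of the G1 to S transition, 4.91 against 6.95. KIF20A, a mitotic kinesin, had 1.39 against 3.19, CENPF, a kinetochore protein, 0.338 against 1.22, both about the level of a typical probe or below, NOP2, which methylates ribosomal RNA, 8.72 against 13.4, and NCL, nucleolin, 11.4 against 18.5. The SRCAP and TIP60 complexes, which contain GAS41, had 13 of 21 genes lower (median log2 -0.16, camera adjusted p = 0.583). Of their members RUVBL2, an ATPase of both complexes, averaged 1.13 against 1.65, near the level of a typical probe, and MORF4L1, a histone-binding subunit of TIP60, differed by log2 -0.26.

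Target genes of p53 had 12 of 24 higher and 12 lower between the same groups (camera adjusted p = 0.937), with TP53I3, an oxidoreductase, at log2 -0.55 and POLH, a DNA polymerase, at log2 -0.60. Among 14 genes of bands 12q13-15, the wider region of chromosome 12 that holds YEATS4, 7 were higher and 7 lower (camera adjusted p = 0.944). CDK4, the cyclin-dependent kinase of early G1, averaged 73.7 against 122. Its log2 difference of -0.74 (SE 0.165) passed when adjusted over the list alone (limma adjusted p = 0.0098) and not over all probes (limma adjusted p = 0.984). OS9, a lectin of the endoplasmic reticulum, differed by log2 0.41. Osteoblast genes had 12 of 18 lower (camera adjusted p = 0.344), among them DLX3 at 0.515 against 1.47 and ALPL at 1.65 against 2.62, all low values.

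Between F7 -Dox and F7 +Dox, which shows what doxycycline removal does without the transgene, no probe passed limma's test in the fit without a replicate block; with such a block EEF1A2, RBM3, TRAF4 and others did, as given among the alternatives. EEF1A2 had the lowest p, at 12.7 against 29.4 (log2 -1.21, SE 0.164, limma adjusted p = 0.341). RBM3, an RNA-binding protein induced by cold, averaged 18.2 against 40.0, TRAF4, an adaptor of receptor signalling, 5.94 against 11.7, and SELENOT, a selenoprotein of the endoplasmic reticulum, 14.9 against 27.5. ZNF281, a zinc finger transcription factor, differed by log2 -0.87. The probes of TRAF4 and ZNF281 both lie in column 6, near an edge. Probes 293005, 339005 and 377005 of column 5, called only with the block, averaged 6.33, 6.28 and 6.18 in F7 -Dox and 10.7 to 12.3 in the other groups. Also called lower only with the block were probes 125005 and 129005 of column 5 and probe 299008 of PHLDA2, in column 8. TRAF4 and ZNF281 still passed with the block and a smooth position trend removed (limma adjusted p = 0.0123 each). That trend was too broad to follow an effect of a few edge columns, so these values do not bear on one. An effect of position on these arrays was not tested. The 5 genes with the smallest p on the higher side were PNKY, NOL7, PDLIM3, TAAR8 and HECA, between log2 0.58 and 0.78 (limma adjusted p 0.93 to 0.94). A second probe of TRAF4 and of NOL7, and 1 of the 3 probes of ZNF281, had the opposite sign. At an unadjusted p under 0.05 there were 2630 probes in the fit without a replicate block, where chance gives 2711. No gene list passed, and the smallest camera adjusted p was 0.407, for mitosis and spindle (17 of 28 higher, median log2 0.37).

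The change on doxycycline removal in B3 minus that in F7 was meant to ask which genes respond through the transgene. Each kind is a single clone. A transgene effect therefore cannot be told from clones that differ in their response to doxycycline itself. Genes of S phase and DNA replication were lower in this difference, with 27 of 30 below 0 and a median log2 of -0.58 (camera adjusted p = 0.0201). Mitosis and spindle genes had 21 of 28 below 0 and a median of -0.47 (camera adjusted p = 0.0143), and ribosome biogenesis 13 of 15 and -0.44 (camera adjusted p = 0.0448). With an estimated correlation between genes none of these calls held (camera adjusted p = 0.991, 0.193 and 0.991). MCM2, a subunit of the replicative helicase, went from 24.4 to 18.2 in B3 and from 17.4 to 20.1 in F7 on removal of doxycycline, by group means. NOP2 went from 13.4 to 8.72 in B3 and from 14.9 to 14.4 in F7. CDC25C, a phosphatase that starts mitosis, CENPF and NOP58, a small nucleolar ribonucleoprotein, had the smallest p of their lists but group means of only 0.903 to 1.84, 0.338 to 1.22 and 0.522 to 1.24, so no size is given for them. None of these genes passed alone. Of the measured genes 20 of 30 for S phase, 13 of 28 for mitosis and 11 of 15 for ribosome biogenesis lay above the median of tested values. The S phase call ended without any 1 of 5 arrays: F7 +Dox replicates 1 and 3, F7 -Dox replicate 2, B3 +Dox replicate 1 and B3 -Dox replicate 3 (camera adjusted p = 0.056, 0.102, 0.106, 0.163 and 0.074), and its median was -0.261 without F7 -Dox replicate 2. The mitosis call ended without F7 +Dox replicate 1 (median -0.292, camera adjusted p = 0.056), and that of ribosome biogenesis without any 1 of 7: F7 +Dox replicates 1 and 3, F7 -Dox replicates 1 and 2, B3 +Dox replicates 1 and 2 and B3 -Dox replicate 3 (camera adjusted p = 0.142, 0.403, 0.0976, 0.136, 0.179, 0.185 and 0.193), with medians of -0.173 without F7 +Dox replicate 3 and -0.29 without B3 +Dox replicate 1.

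No single probe passed limma's test of this difference in the fit without a replicate block. In that fit 1701 had an unadjusted p under 0.05, where chance gives 2711. With such a block a few probes passed, as given among the alternatives. POLI had the smallest p among named genes, from 14.6 to 7.48 in B3 and from 7.13 to 9.99 in F7 (difference log2 -1.45, SE 0.214, limma adjusted p = 0.416). The others on the lower side were PNKY, OTOP1, GAPDHS and ZBED3, and those on the higher side PSAT1, PHLDA2, LMO4, MAFF and SETD5, all with a limma adjusted p of 1; a second probe of SETD5 had the opposite sign. PSAT1, an enzyme of serine synthesis, went from 18.7 to 25.6 in B3 and from 11.5 to 7.61 in F7. MAFF, a small Maf transcription factor, went from 4.83 to 9.51 in B3 and from 4.74 to 4.44 in F7. ZBED3 was near 1 or below in every group, and probe 299008 of PHLDA2 lies in column 8, near an edge.

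The arrays labelled B3 -Dox and F7 -Dox, compared to separate the transgene from doxycycline, differed most in CALCR, the calcitonin receptor. It averaged 1.71 ± 0.395 in B3, near the level of a typical probe, and 90.4 ± 6.65 (SD, n = 3 each) in F7 (limma adjusted p = 1.74e-07). No fold is given, because whether the probe lay above background in B3 is not known. WIPI1, a phosphoinositide-binding protein of autophagy, rose from 2.86 to 20.9 (log2 2.90, SE 0.289, limma adjusted p = 0.00399); its second probe had the opposite sign, and averaged over both probes the difference was log2 1.38 and not called (limma adjusted p = 0.433). PSAT1 was 3.34-fold higher (limma adjusted p = 0.000912), and CFB, complement factor B, RBM3 and YPEL5 were 2.85-fold, 2.78-fold and 2.74-fold higher (limma adjusted p = 0.0406, 0.00761 and 0.0359). PTPRK, a receptor tyrosine phosphatase, averaged 19.8 against 39.6 and was lower (limma adjusted p = 0.0228). Clone and transgene change together here, and these genes differed the same way with doxycycline present. In B3 +Dox against F7 +Dox, PSAT1 averaged 18.7 against 11.5, CFB 11.4 against 4.46 and YPEL5 6.24 against 3.44. PTPRK averaged 20.4 against 36.7 there, and RBM3 56.9 against 40.0. On removal of doxycycline RBM3 fell to 18.2 in F7 and to 50.7 in B3. In all, 18 probes were called, 15 higher and 3 lower, 8 of them without a listed gene. Among the higher ones, probe 213005 of column 5 averaged 1.15 in F7 -Dox and 3.01 to 3.45 in the other groups. Probe 327112 of column 112 averaged 2.16 in F7 -Dox and 4.33 to 5.89 in the other groups. Both lie at or near an edge, and an effect of position was not tested. The split into higher and lower calls was 37 and 17 after quantile normalization and 16 and 11 after scaling to the 75th percentile. With a replicate block 390 were called, 271 higher and 119 lower. That majority turned when a position trend and each array's level were also removed, as given among the alternatives. Between 4 and 6 probes were called when 1 array of either group was left out: 4 without F7 -Dox replicate 1, 5 without each of F7 -Dox replicates 2 and 3 and B3 -Dox replicate 3, and 6 without each of B3 -Dox replicates 1 and 2. CFB, YPEL5 and PTPRK lost the call in all 6 of these, and RBM3 in 4 of the 6. Without the mean-variance trend WIPI1, PSAT1, CFB, RBM3, YPEL5 and PTPRK all lost the call (limma adjusted p 0.128 to 0.564), and with only the arrays compared CFB, RBM3, YPEL5 and PTPRK did (limma adjusted p 0.115 to 0.214).

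In the same comparison PSAT1 was the only called gene among 23 of the ATF4 and amino acid stress list, of which 16 were higher (median log2 0.54, camera adjusted p = 0.137). The osteoblast list (7 of 18 higher, camera adjusted p = 0.922) had no called gene. DLX5, a homeobox factor of bone, averaged 2.03 against 0.827, both low values, and COL1A2, a chain of type I collagen, differed by log2 -0.61. The p53 targets (14 of 24 higher, camera adjusted p = 0.922) had none either, with CDKN1A, an inhibitor of cyclin-dependent kinases, at log2 0.71 and TP53I3 at log2 -0.59.

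Against F7 +Dox, the arrays labelled B3 -Dox had 35 called probes, 28 higher and 7 lower. With a replicate block 772 were called, 633 higher and 139 lower. That majority turned when a position trend and each array's level were also removed, as given among the alternatives. CFB rose 2.31 on the log2 scale (SE 0.215, limma adjusted p = 0.0014). WIPI1 was higher, at 20.9 against 1.68, and CALCR lower, at 1.71 against 90.7 (limma adjusted p = 0.000275 and 1.84e-07), with the lower value near that of a typical probe in both. MMP9 was higher by log2 1.63 and SFN lower by 0.93 on that scale (limma adjusted p = 0.014 and 0.0302), from 46.6 to 24.5 for SFN. This comparison changes both clone and doxycycline, and SFN averaged 27.6 in F7 -Dox. Without B3 -Dox replicate 2 the count was 5, without B3 -Dox replicate 3 it was 11, without F7 +Dox replicate 1 it was 13 and without B3 -Dox replicate 1 it was 17.

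The study's design looks for genes that set B3 -Dox apart from all 3 other groups, and 3 probes were called higher against each of them. They were probes 73082, 62066 and 318014, named here after their values were seen because the count is small, and none has a listed gene. Probe 73082 averaged 37.3 in the arrays labelled B3 -Dox, 4.05 in B3 +Dox, 9.47 in F7 -Dox and 4.21 in F7 +Dox. Probe 62066 averaged 79.5, 18.2, 24.3 and 20.1 in the same order, and probe 318014 averaged 43.5 in the arrays labelled B3 -Dox and 18.6 in B3 +Dox. The 3 comparisons share the B3 -Dox arrays. Unchanged groups simulated with those shared arrays gave 0 such probes in each of 20 runs, and independent lists of these sizes would share 5.79e-07. The simulation drew each probe independently, without replicate effects or an outlying array. It called a mean of only 0.1 probes for B3 -Dox against F7 -Dox, so a 0 overlap was nearly certain. Lists that share arrays are not independent. Neither value therefore excludes chance. Leaving out 1 array left 1, 2 or 4 probes: 4 without F7 +Dox replicate 3, 2 without B3 +Dox replicate 2, and 1 without each of the others. All of this is from the fit without a replicate block. With such a block 32 probes were set apart, 31 higher and 1 lower, 15 of them without a listed gene. MMP9, NPR1 and PLCXD2 were among the higher ones, and the lower one was MCM4.

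The clones also differed with doxycycline present, when the transgene is silent by design. CALCR averaged 1.61 ± 0.195 in B3 +Dox and 90.7 ± 22.6 in F7 +Dox (SD, n = 3 each, limma adjusted p = 1.58e-07), and WIPI1 9.52 ± 2.22 against 1.68 ± 0.512 (SD, n = 3 each, limma adjusted p = 0.0295). In the fit without a replicate block these were the only 2 called probes. WIPI1 lost its call without F7 +Dox replicate 2 or 3 and without B3 +Dox replicate 1 or 2 (limma adjusted p 0.061, 0.0854, 0.361 and 0.259). Its second probe had the opposite sign, and WIPI1 was not called when averaged over both (log2 1.02, limma adjusted p = 0.727), without the mean-variance trend (0.383) or with only the arrays compared (0.857). FOS, a transcription factor of the immediate early response, averaged 4.98 against 1.497, and LMOD1, an actin nucleator of smooth muscle, 68.9 against 27.9. BPIFB4 and SLC38A3, a glutamine transporter, differed by log2 1.13 and 1.11. Without a replicate block none of these 4 passed (limma adjusted p 0.065 to 0.0821), nor did PTPRK, MUC1, ACVR2B and ADAM2 on the lower side (limma adjusted p 0.0994 to 0.515). With such a block 186 probes were called. FOS, LMOD1, BPIFB4, SLC38A3, PTPRK and MUC1 then passed, as given among the alternatives. FOS and LMOD1 passed after quantile normalization (limma adjusted p = 0.0454 each), BPIFB4 with the floor at the 10th percentile (0.0422), and BPIFB4 and SLC38A3 without the dimmest 25% of probes (0.0421 and 0.0438). No gene list passed, and the smallest camera adjusted p was 0.509.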

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

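The test of ribosome biogenesis alone and the list tests without 1 array were chosen after the result was seen; the test with an estimated correlation was planned, but its use as an explanation was not, and the medians without F7 +Dox replicate 3 had been seen before the arrays were ranked. In 3 gene lists the change on doxycycline removal passed the test of the difference between the clones at the preset correlation: the median log2 difference was -0.575 for S phase and DNA replication, -0.474 for mitosis and spindle and -0.436 for ribosome biogenesis. With the correlation estimated none passed (camera adjusted p = 0.991, 0.193 and 0.991). The medians were -0.31, -0.16 and -0.15 in B3 and 0.20, 0.37 and 0.16 in F7, where no list passed within either clone (smallest camera adjusted p 0.229 and 0.407).

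Leaving out the array of F7 +Dox replicate 3 moved the median towards 0 further than any other array in 1 of the 3 lists, which argues against that array as the whole cause for S phase and mitosis. Without it the median was -0.417 for S phase, whose call ended (camera adjusted p = 0.102), and -0.362 for mitosis (camera adjusted p = 0.0158), while F7 -Dox replicate 2 moved S phase to -0.261 and F7 +Dox replicate 1 moved mitosis to -0.292. For ribosome biogenesis 0 of the other 11 arrays moved it as far, to -0.173, and the call ended (camera adjusted p = 0.403), as it did without any 1 of 6 other arrays. With the replicate block and without F7 +Dox replicate 3, ribosome biogenesis kept its call (-0.287, camera adjusted p = 0.0435), as did S phase (-0.575, camera adjusted p = 0.000977), and mitosis did not (-0.328, camera adjusted p = 0.0516), so the part of that array in ribosome biogenesis stays open. Genes of a list that vary together from array to array may account for all 3: with the correlation estimated, the smallest camera adjusted p was 0.193, and with the replicate block it was 0.106 for S phase and 0.148 for each of the others, and an effect of the transgene, which the design names, stays open and was not tested, since YEATS4 itself was not higher in the arrays labelled B3 -Dox.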

How the results depend on the processing

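The alternatives that combine the replicate block with another change, and those without F7 +Dox replicate 3 where a comparison does not contain it, were chosen after the data were seen. Counts of called probes are given in a fixed order: B3 -Dox against B3 +Dox, F7 -Dox against F7 +Dox, the difference of these, B3 -Dox against F7 -Dox, B3 -Dox against F7 +Dox, B3 +Dox against F7 +Dox, and the overlap of the 3 comparisons of B3 -Dox. As reported they were 5, 0, 0, 18, 35, 2 and 3. Quantile normalization gave 20, 0, 4, 54, 100, 9 and 14, and scaling to the 75th percentile 9, 0, 0, 27, 45, 2 and 2. Leaving out the dimmest 25% of probes gave 5, 0, 0, 33, 41, 5 and 3, the floor at the 10th percentile 9, 0, 0, 28, 42, 5 and 4, and probes with all 12 values 5, 0, 0, 25, 36, 2 and 3. Averaging per gene, which drops probes without a listed gene, gave 0, 0, 0, 15, 21, 1 and 0. Without the mean-variance trend the counts were 1, 0, 0, 1, 3, 1 and 0. With only the arrays compared, which leaves fewer arrays to estimate the spread, they were 1, 0, 4, 3 and 1 for the 5 comparisons of 2 groups. The cause of the other changes was not tested. The split into higher and lower calls moved with the scaling: for B3 -Dox against F7 -Dox it was 15 and 3 as reported, 37 and 17 after quantile normalization and 16 and 11 after scaling to the 75th percentile, and after quantile normalization it was 19 and 1 for B3 -Dox against B3 +Dox and 8 and 1 for B3 +Dox against F7 +Dox.

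Leaving out 1 array of the groups compared gave 1 to 2, 0 to 1, 0 to 1, 4 to 6, 5 to 25, 1 to 6 and 1 to 4 probes in the same order. For B3 -Dox against B3 +Dox 2 probes were left without B3 +Dox replicate 2 and 1 without each of the other 5 arrays. F7 -Dox against F7 +Dox had 1 call without F7 +Dox replicate 1 or 2, the difference had 1 without F7 +Dox replicate 3, and B3 +Dox against F7 +Dox had 6 without F7 +Dox replicate 2, 3 without F7 +Dox replicate 1 and 1 without B3 +Dox replicate 1 or 2. Without F7 +Dox replicate 3, which neither comparison contains but which enters the shared estimate of the spread, B3 -Dox against B3 +Dox had 9 calls and B3 -Dox against F7 -Dox had 47.

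The replicate number as a block gave 41, 33, 10, 390, 772, 186 and 32 called probes, and each call made without the block was also made with it. Named genes that passed with it and not as reported were EEF1A2 (limma adjusted p = 0.0266), RBM3 (0.00761), TRAF4 (0.0266), SELENOT, ZNF281, NOL7 and TAAR8 in F7, MMP9 (0.000408), NPR1, PLCXD2, LMO4, LLCFC1, POLI, SFN and PBK in B3, POLI (0.0153) in the difference, and FOS, LMOD1, BPIFB4, SLC38A3, PTPRK (0.00424) and MUC1 (0.00848) in B3 +Dox against F7 +Dox. The block was not taken as the main design. Over the 49177 probes with all values, arrays of the same number deviated together with r from 0.0337 to 0.0981, under the limit of 0.1 set for pairing, and arrays of other numbers with r from -0.0671 to 0.0144. So each pair of the same number correlated more than any pair of other numbers, although under that limit. This comes from the data and not from the labels, which give no shared day or batch. The outcome depends on the probes used: r was 0.0874 to 0.233 for probes with a mean log2 of at least 0, 0.172 to 0.516 at 1.5 and 0.22 to 0.704 at 3. No probe set was fixed beforehand and the calls of both fits had been seen, so the check was read over all probes. Block and quantile normalization together gave 28, 0, 7, 143, 397, 73 and 22. With the block and without F7 +Dox replicate 3 the counts were 60, 34, 15, 561, 579, 118 and 41, and with a smooth trend over array position removed 43, 41, 14, 394, 622, 98 and 27. That trend's removal also moved the split into higher and lower calls. With the block the split was 271 and 119 for B3 -Dox against F7 -Dox, 633 and 139 for B3 -Dox against F7 +Dox, 168 and 18 for B3 +Dox against F7 +Dox and 15 and 18 for F7, and after removal 180 and 214, 281 and 341, 56 and 42, and 9 and 32. The majority turned from higher to lower only for B3 -Dox against each F7 group. At an unadjusted p under 0.05 the block gave 4279 probes for F7 -Dox against F7 +Dox and 2833 for the difference, where chance gives 2711. Without the block there were 2630 and 1701, and 1579 for B3 -Dox against B3 +Dox, all under that number. A lack of calls in the fit without the block therefore says little about an absence of change. Of the 33 probes called with the block in F7, 19 remained without F7 +Dox replicate 3 and 0 after quantile normalization. With the block, camera also called S phase and DNA replication (adjusted p = 0.0109) and ribosome biogenesis (adjusted p = 0.0234) in B3 -Dox against B3 +Dox, which were 0.202 and 0.224 with an estimated correlation.

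The YEATS4 difference stayed within -0.22 to 0.13 on the log2 scale when 1 array was left out, above 0 without B3 -Dox replicate 1 (0.051), B3 -Dox replicate 3 (0.022) or B3 +Dox replicate 2, and was 0.045 with the block and the position trend removed; its adjusted p was 0.982 or more throughout. Of 1388 values of 71 named gene results under the alternatives, 1242 kept their direction and side of the threshold, 95 newly passed, 50 no longer passed and 1 changed sign: COL1A2 between B3 -Dox and F7 -Dox, log2 0.76 when averaged per gene. CALCR kept its call under every alternative run. Array intensities carry no count, so depth set no limit, but dim probes near the background have large spreads on the log2 scale.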

Other observations

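The tests of probe saturation, of the probe's place and of a swap by the YEATS4 level were chosen after the YEATS4 values were seen, the correlation of 0.23 had been seen before its labellings were ranked, and the genes in the next paragraph were chosen after their values were seen.

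Several further genes were called between the arrays labelled B3 -Dox and F7 +Dox. LMOD1 averaged 79.5 against 27.9 (log2 1.47, limma adjusted p = 0.012). ANXA13, an annexin of intestinal epithelium, averaged 123.2 against 40.2, and SLC44A4, a choline transporter family member, 17.0 against 6.99. FOS averaged 5.68 against 1.497 and NKX2-3, a homeobox factor of gut and spleen, 13.96 against 4.98. UBE2Q1, a ubiquitin-conjugating enzyme, was lower, at 39.7 against 79.3 (log2 -0.99, limma adjusted p = 0.0352). Probes 53073, 254021 and 4091, without a listed gene, averaged 153.4, 153.0 and 130.7 in the arrays labelled B3 -Dox and between 35.7 and 54.4 in the 3 other groups.

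YEATS4, the gene the plasmid of clone B3 should express, was level between the arrays labelled B3 -Dox and B3 +Dox. Saturation is argued against, because each array's highest value was at least 26.9 times its YEATS4 value. With a probe that reads the transgene, swapped doxycycline labels in clone B3 alone would put YEATS4 lower in the arrays labelled B3 -Dox, where the 95% interval of the log2 difference ended at -0.472, but whether the labels are swapped stays open. Across bright probes the responses of both clones correlated at 0.23 (genes are not independent replicates), and 3 of 20 labellings of the B3 arrays, the real one included, were as high. All 5 probes called in B3 differed the same way in F7. EEF1A2 differed by log2 -1.31 in B3 and -1.21 in F7 (SE 0.164), and probe 73082 by 3.20 and 1.20. Probes 62066, 53073 and 318014 differed in F7 by only 0.20 to 0.29, which says little about the labels. A probe outside the part of the gene that the transgene carries may account for it and stays open, because the array has 1 probe with that symbol, and a failure of induction was not tested.

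F7 +Dox replicate 3 stood apart from the other arrays. A local defect on the array surface is a candidate cause: in the edge region, 379 middling probes that played no part in finding it had a median deviation of log2 -0.391 relative to the rest of that array, against -0.096 to 0.0596 on the other 11 arrays. Weaker labelling of the whole array stays open: outside the region 0.299% of bright probes lay more than 4-fold from the median, against 0.229% on B3 +Dox replicate 3 (ratio 1.31, 95% interval from counting 0.598 to 2.93) and 0.0177% to 0.106% on the other 10 arrays. No biological explanation was tested, because replicates of a group differ in nothing the labels give.

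Other splits of the arrays were counted for each comparison. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split of B3 -Dox and B3 +Dox called 5 probes and the highest other split 0; the real counts for B3 -Dox against F7 -Dox, B3 -Dox against F7 +Dox and B3 +Dox against F7 +Dox were 18, 35 and 2, and the highest other count was 0 each time, so 1 of 10 splits reached the real count in each. For F7 -Dox against F7 +Dox and for the difference between the clones' responses the real count was 0, which every split reaches (10 of 10 and 100 of 100 drawn), so the splits decide nothing there. For the probes set apart in B3 -Dox, 1 of 100 splits drawn, the real one, gave 3 and the highest other gave 0. These splits mix clones and treatments, so a real difference at a probe widens its spread in the other splits. A count of 0 was therefore likely beforehand, and the splits do not exclude chance as the source of the 3.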
